A study of Triticum aestivum with 4 samples.

How the data were processed

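Messenger RNA from developing wheat seed was measured on 4 Affymetrix wheat GeneChip arrays. The samples were the parents of a mapping population, the genotypes AC Domain and RL4452, with 2 biological replicates each, per the labels. The parents and 39 lines of the population were grown in the field as rows of 1.47 m with 3 field replications in a lattice of 49 entries, and seed was taken 5 days after anthesis. Poly(A) RNA was enriched from total RNA, copied into biotin-labelled cRNA and hybridised to 1 array per sample, per the labels' protocols.

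The deposited values are probe set intensities from RMA, per the submitters' processing notes, which here give no version. RMA corrects the background, normalises the probes of all arrays to 1 distribution and summarises each probe set. The deposited intensities were on a linear scale, from 4.74 to 25900, and not as the log2 values that RMA usually returns; which arrays were normalised together is not given in the sources used here. Median intensity per array ran from 31.9 to 33.7. The run files of the instrument, which hold settings and no measurement, were read only for the project, the scan day and the wash record of each array.

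The deposited intensities were log2-transformed and no further normalisation was applied. The table held 61290 probe sets. The 175 control probe sets were left out, and 61115 wheat probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with genotype as the only factor, a two-sided test and a Benjamini-Hochberg adjusted p under 0.05. Differences are RL4452 minus AC Domain, and errors are SDs over 2 arrays or standard errors of the fit. The number of arrays limits the precision: the fit had 2 residual degrees of freedom per probe set and took 2.97 more from the common prior. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so no single value has an exact test. On simulated data of the same size, with 200 probe sets changed, limma recovered 0 of 65 changes of 1 log2 unit, 7 of 60 of 2 units and 64 of 75 of 4 units, with 4 false calls. The simulated errors were independent, alike in both genotypes and without a project effect, so that these counts need not hold for the arrays here.

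A level of background was taken from 23 negative control probe sets, whose 95th percentile over the 4 arrays was 4.48 on the log2 scale (an intensity of 22.3).

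The run files named 2 projects. The replicate 1 arrays of both genotypes shared 1 project and the replicate 2 arrays the other, and the project in the run files is where the pairing comes from. Whether a project was a batch in the laboratory is not stated. Arrays with the same number deviated together from their genotype means (r = 0.398 across probe sets, which are not independent replicates). Each array was scanned on a day of its own, so scan day could not be set as a block. The wash record of the RL4452 replicate 2 array was marked as aborted and held 0 wash steps, against 16 for each other array. The fit with the project as a block stands beside the count of calls, and the difference within each project beside the results it bears on.

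Names came from a platform annotation table, updated through gene identifiers to the RefSeq genes of the IWGSC CS RefSeq v2.1 assembly, of which no coordinates were used. It gave 1273 probe sets 1 gene each, 771 genes in all, of which 770 were found in the RefSeq table. No probe set had several genes, and 59842 wheat probe sets have no name here. Most of these genes carry a LOC symbol, and 102 have a descriptive symbol or synonym.

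Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule took, per direction, up to 12 genes with the largest difference among probe sets past the threshold whose arrays did not overlap between genotypes and that had exactly 1 gene, with 1 probe set per gene, plus the 2 largest without a name. From each list it took up to 4 members with the smallest p. The 25 lists were search patterns for names. The annotation held symbols and no descriptions, so that 5 lists found a member and 1 could be tested. The lists were therefore extended by symbols, and lists of tubulins and translation genes were added. This was done after the annotation table and the control probe values had been seen and before any difference between genotypes was computed. The extended lists numbered 27, of which 18 had a member and 10 had the 5 members needed for a set test. Those without a member were grain softness, cell cycle, nucellus and pericarp proteolysis, endosperm transfer cells, resistance receptors, ribosomal proteins, flowering and MADS genes, dormancy and transposons. The ribosomal protein genes RPS29 and RPL9 stood in the list of translation genes. Sets were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and with fry, adjusted over the lists tested.

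Probe set IDs of this array carry a transcript cluster and a sub-cluster number. Agreement within a cluster was measured over pairs of probe sets brighter than the median, and shares were given 95% intervals from 2000 bootstrap draws of whole clusters. The alternatives tried were the project block, leaving out each array in turn, a filter on dim probe sets, median centring, a further quantile normalisation, other forms of eBayes, an ordinary equal-variance statistic, a stricter threshold, a minimum fold, other sets of probe sets and other set tests.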

Results

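Gene expression was profiled in developing seed of bread wheat, Triticum aestivum, 5 days after anthesis, in the genotypes AC Domain and RL4452. Both are parents of a mapping population, and the series asks which transcripts differ in level between them. Each genotype was represented by 2 biological replicates, with 1 array each, and 61115 wheat probe sets were measured. Between 58.0% and 60.1% of the probe sets on an array lay above the 95th percentile of the negative controls.

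Granule-bound starch synthase I (GBSS-I, the waxy gene, LOC543395), which makes amylose in the endosperm, was 5.21-fold higher in RL4452 than in AC Domain. The gene had 1 named probe set. Its log2 intensity was 10.58 ± 0.18 in RL4452 and 8.20 ± 0.39 in AC Domain (SD, n = 2; limma, adjusted p = 0.0344). GLU1A (LOC780595), a beta-glucosidase gene, was 4.85-fold higher in RL4452 (9.86 ± 0.01 against 7.58 ± 0.24, SD, n = 2; limma, adjusted p = 0.0196). LOC542941 and LOC543060, which have no descriptive symbol, were 4.88-fold and 3.43-fold higher. These were the only 4 genes with a name among the probe sets that were higher in RL4452 and past the threshold.

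The genes lower in RL4452 were led by LOC542839, which was 25.9-fold brighter in AC Domain (9.21 ± 0.18 against 4.52 ± 0.05, SD, n = 2; limma, adjusted p = 0.00458). LOC543235 was 21.9-fold and LOC543492 15.5-fold brighter in AC Domain. The RL4452 means of LOC542839 and LOC543235 (4.52 and 4.61) lay close to the negative control level of 4.48, so that their folds depend on that background. LOC780602 (9.13-fold), LOC778392 (8.76-fold) and LOC100049055 (7.96-fold) followed. LOC543448, LOC542826, LOC542847 and LOC543104 were between 3.02-fold and 3.40-fold brighter in AC Domain. The RL4452 means of LOC100049055 and LOC543448 (4.79 and 4.77) were above 4.48 but below the highest negative control (4.93), so that their folds may also depend on background. None of these 10 genes has a descriptive symbol.

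The largest differences were measured in probe sets without a name. Ta.556.2.A1_at and Ta.10945.2.A1_a_at were 173-fold and 169-fold higher in RL4452. Ta.28744.1.S1_at and TaAffx.105083.1.S1_at were 188-fold and 127-fold brighter in AC Domain. In each of these 4 probe sets the dimmer genotype lay near or below the negative control level, and the brighter one at 10.00 or above on the log2 scale, so that the folds and their order depend on that background.

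**Figure D1:**
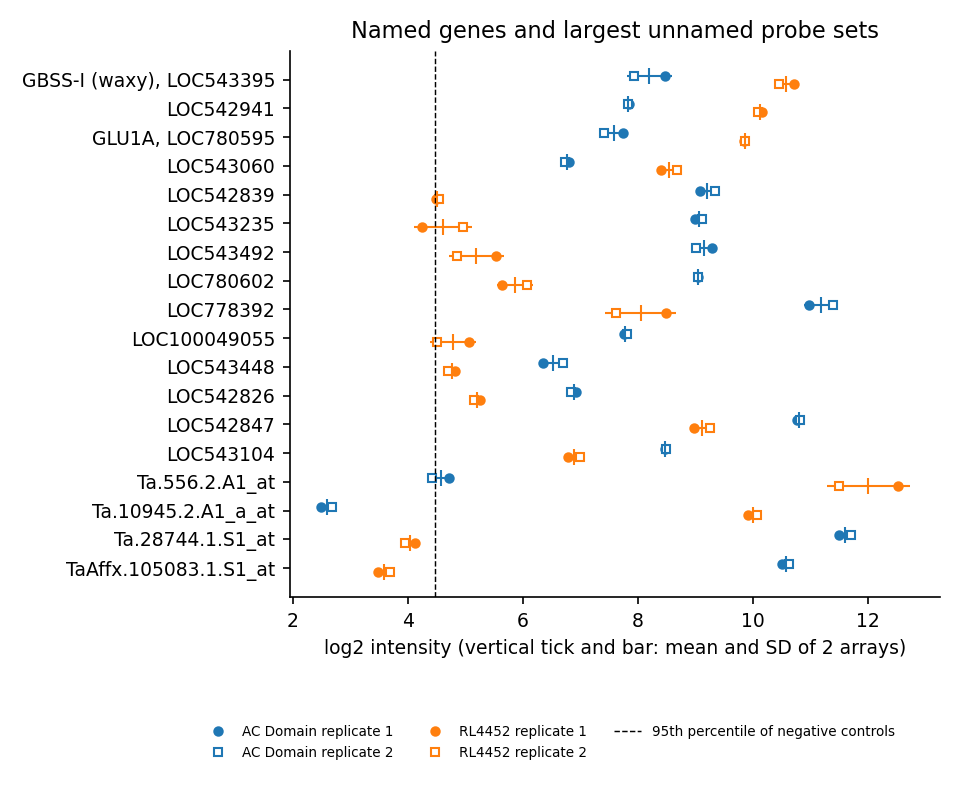
Log2 intensity (x axis) of the 14 named genes and the 4 largest unnamed probe sets (y axis), with 1 symbol per array, the mean and SD of the 2 arrays of each genotype, and the 95th percentile of the negative controls as a dashed line. The 2 arrays of AC Domain (blue) and of RL4452 (orange) do not overlap in any row, and LOC542839 in RL4452 sits at 4.52, next to the dashed line.

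Over all probe sets, 489 passed the threshold, which is 0.800% of those tested. Of these, 137 were higher and 352 lower in RL4452, so that 72.0% of the calls were lower. Every call was at least 2.66-fold, the median was 6.70-fold and the largest, against a signal below the negative control level, 188-fold. A difference of at least 16-fold was found in 88 probe sets, 30 higher and 58 lower in RL4452. In 169 calls the dimmer genotype was at or below the negative control level: RL4452 in 119 and AC Domain in 50. These were 33.8% of the lower and 36.5% of the higher calls (Fisher's exact test, two-sided, p = 0.597). The 2 arrays of 1 genotype lay beyond both of the other in 489 of 489 calls and in 39.9% of all probe sets, where chance gives 33.3%. At an unadjusted p under 0.05, limma gave 5601 probe sets, 2288 higher and 3313 lower in RL4452.

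**Figure D2:**
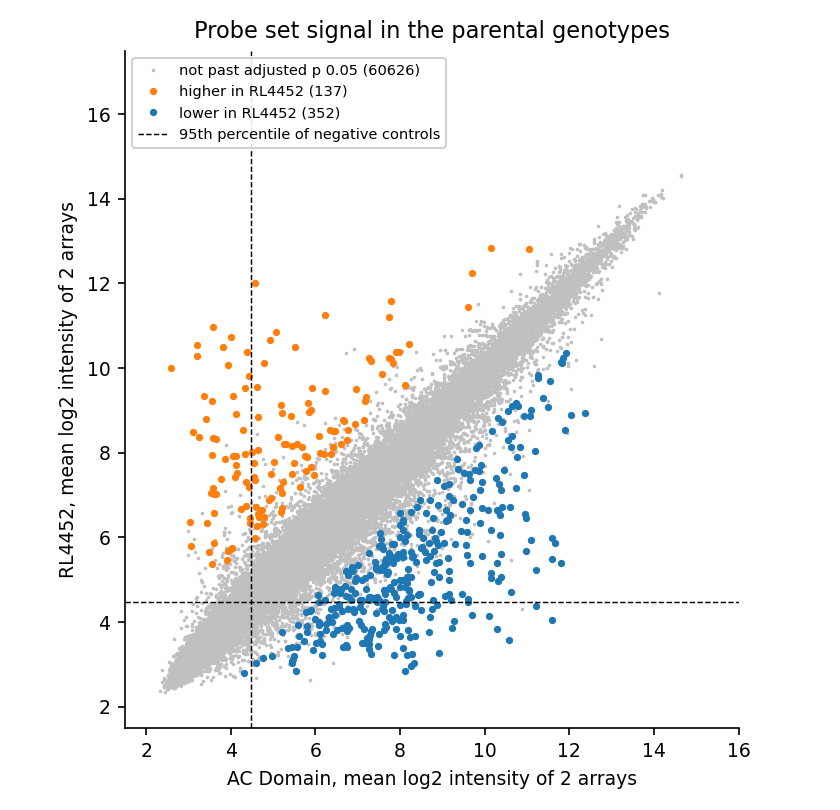
Mean log2 intensity of the 2 AC Domain arrays (x axis) against that of the 2 RL4452 arrays (y axis) for 61115 probe sets, with the 137 probe sets higher in RL4452 in orange, the 352 lower in blue, the rest in grey, and the 95th percentile of the negative controls (4.48) as dashed lines. Both colours reach to the left of or below the dashed lines, where 1 genotype is at the level of the negative controls.

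With the project as a replicate block, 667 probe sets passed, 172 higher and 495 lower in RL4452. In that fit LOC778392 (adjusted p = 0.0568) and LOC543448 (adjusted p = 0.0530) missed the threshold, and the other named genes passed. The difference within the project of replicate 1 and that within the project of replicate 2 had the same sign in 489 of 489 calls, which had been chosen for agreement between replicates. They correlated at r = 0.602 across all probe sets, which are not independent replicates. For GBSS-I they were 2.23 and 2.53 on the log2 scale, and for LOC542839 they were -4.60 and -4.79. The count depended on which pair gave the spread. Without AC Domain replicate 1 or without AC Domain replicate 2, limma called 0 probe sets (2999 and 2441 at an unadjusted p under 0.05), because the spread then came from the RL4452 pair alone. The sizes stayed close: GBSS-I had 2.66 and 2.10 in these fits against 2.38 with all arrays, and LOC542839 had -4.82 and -4.56 against -4.69. Without RL4452 replicate 1 or 2, with the spread from the AC Domain pair alone, limma called 1031 and 998.

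The spread between replicates differed between the genotypes. The log2 difference between the 2 arrays had an SD of 0.327 across probe sets in AC Domain and 0.528 in RL4452. Between 1 array of AC Domain and 1 of RL4452 it had an SD between 0.537 and 0.643 in the 4 pairs of arrays. The first principal component held 56.9% of the variance and separated the genotypes, and the second held 34.1% and separated the replicate 1 arrays from the replicate 2 arrays in both genotypes, and so the 2 projects. The scores on it were -59.2 and 68.9 in RL4452 and -26.1 and 16.4 in AC Domain.

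GBSS-I was the only 1 of the 157 probe sets in the gene lists that passed the threshold over all probe sets. That share is close to the 0.800% called among all probe sets tested, and so does not set the lists apart. Among the 4 probe sets for starch synthesis GBSS-I was also the 1 past the threshold adjusted over the list alone. AGP-S and AGA.1, which encode subunits of the enzyme that makes ADP-glucose, had differences of -0.21 and 0.37 (log2; adjusted p = 0.780 and 0.731), and a second AGA.1 probe set had 0.05. For fructan and sugar metabolism all 5 probe sets were higher in RL4452 as deposited and 4 after either rescaling (median 0.78; camera, adjusted p = 0.118). They belong to 3 genes. The median was 0.10 without RL4452 replicate 1 (4 of 5 higher), 0.52 without AC Domain replicate 2 and 1.35 without RL4452 replicate 2. It was 1.27 within the project of replicate 1 and 0.20 within that of replicate 2. Within this list 6-FEH, a fructan exohydrolase, had 3 probe sets, with 1.23 ± 0.18, 0.78 ± 0.46 and 1.16 ± 1.11 (log2, standard error). The first passed when adjusted over the list alone, but not over all probe sets (adjusted p = 0.0855), and the third was -0.45 without RL4452 replicate 1. The control probe sets for sucrose synthase, which lie outside this list, were lower in RL4452 and did not pass. Their 3', middle and 5' probe sets had -0.92 ± 0.17, -1.01 ± 0.66 and -0.28 ± 0.72 (log2, standard error).

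All 18 probe sets for the core histones H2A and H2B were higher in RL4452, by a median of 0.28 on the log2 scale, and camera placed the list above the other probe sets (adjusted p = 0.00116). The adjusted p of camera was 0.710 with an estimated correlation. It was 0.345 with fry, which asks whether the list differs at all and not whether it lies above the other probe sets. Of the members, 0 passed the threshold alone (2 at an unadjusted p under 0.05 with limma). The largest differences were H2A-2 (0.86) and wcH2B-8 (0.49). The 18 probe sets belong to 5 genes. With the project as a replicate block the adjusted p of camera was 0.00190, and the median was 0.23 within the project of replicate 1 (17 of 18 higher) and 0.37 within that of replicate 2 (18 of 18 higher). Without RL4452 replicate 2 the adjusted p was 0.166 with a median of 0.19, and without RL4452 replicate 1 the median was 0.42. With 1 probe set per gene the adjusted p was 0.226 and the median 0.31. On the same arrays the 18S rRNA control differed by -2.95, and whether this bears on the histones was not tested.

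Seed storage proteins, the gliadins, glutenins and avenin-like proteins of the later endosperm, had 17 probe sets. Of these, 14 were higher in RL4452 as deposited and 12 after either rescaling (median 0.14, adjusted p = 0.309 with camera), and 12 to 16 when 1 array was left out. 5 of the 17 were above the negative control level, and 0 passed the threshold (1 at an unadjusted p under 0.05 with limma). The 7 probe sets that the fixed patterns found gave an adjusted p of 0.120 with camera. Among 13 probe sets for protease, amylase and xylanase inhibitors, 0 passed over all probe sets (5 at an unadjusted p under 0.05 with limma) and 4 when adjusted over the list alone. Of these, 3 were alpha-amylase/trypsin inhibitors (ATI) with -1.10, -0.78 and -1.35 on the log2 scale, the first against an RL4452 mean of 4.34, which is below the negative control level. The other ATI probe set, of the same gene (LOC543286) as the last 2 of these and below the negative control level in both genotypes, had -0.02. The remaining 1 was the xylanase inhibitor XIP-I with 0.76, and its second probe set had 0.58. In this list 6 of 13 were higher in RL4452, and 4 to 10 when 1 array was left out (camera, adjusted p = 0.452), with 7 of 13 above the negative control level.

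The small heat shock protein gene hsp16.9A had a difference of -2.86 ± 0.41 (log2, standard error; adjusted p = 0.0817), and its AC Domain arrays were apart from each other (6.77 ± 0.83, SD, n = 2). Its RL4452 mean of 3.91 lay below the negative control level of 4.48, so that the size of the difference depends on that background. It passed when adjusted over the list alone, with 2 members, and over all probe sets after the filter on dim probe sets (adjusted p = 0.0422) and with an intensity trend (adjusted p = 0.0377). The other member, the chaperone-associated FKBP70, had -0.39. For hormone metabolism all 4 probe sets, of gibberellin 20-oxidases, were higher in RL4452 under every scaling and 3 of 4 without RL4452 replicate 1, led by GA20ox1d with 0.98 (adjusted p = 0.393). They belong to 3 genes, and 2 of the 4 were above the negative control level. Probe sets for photosynthesis were split, with 15 of 36 higher in RL4452 (median -0.02; camera, adjusted p = 0.734), and 12 to 20 of 36 when 1 array was left out. Of these, 28 belong to 1 gene, rbcl (LOC100049018), and 15 of the 36 were above the negative control level. The defence list had 3 of 8 higher (median -0.16; adjusted p = 0.389), with 4 of 8 above the negative control level, and its thionin THI1.1 had 2 probe sets with -1.30 and -0.50 (adjusted p = 0.415 and 0.620). The first had -1.86 without RL4452 replicate 1, where it passed the threshold (adjusted p = 0.0304), and -0.74 without RL4452 replicate 2 (adjusted p = 0.203). For redox and detoxification 4 of 12 were higher as deposited and 7 after quantile normalisation (adjusted p = 0.735), and 5 to 8 when 1 array was left out.

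Markers of other seed and flower stages gave 0 calls with limma, and 0 at an unadjusted p under 0.05. With 0.800% of all probe sets called, lists of 10 and 4 probe sets were likely to give 0 calls, so that this says little about stage. Late embryogenesis genes, which mark the maturing embryo, had 9 of 10 probe sets higher in RL4452 as deposited and 8 after either rescaling (median 0.20; camera, adjusted p = 0.317), with 3 of 10 above the negative control level. Within the project of replicate 1, 4 of these 10 were higher (median -0.06), and within that of replicate 2, 9 of 10 (median 0.45). Without RL4452 replicate 2, 5 of 10 were higher, with a median of 0.01. RAFTIN genes of the anther had 4 probe sets, 1 of them above that level, with differences from -0.15 to 0.34. Tubulins (8 of 10 higher as deposited, 4 of 10 after median centring; adjusted p = 0.735) and translation genes (4 of 9 higher as deposited; adjusted p = 0.317) had 0 calls, and 1 probe set each at an unadjusted p under 0.05 with limma. The translation probe set was of RPS29, with -1.84 (log2, limma adjusted p = 0.245) and an RL4452 mean of 3.98, below the negative control level. A second RPS29 probe set had 0.28. Beta-amylase BMY1 (0.17), LTP3 of lipid transfer (0.43 and -0.30), the cell wall gene XTH (0.23) and COMT1 of phenylpropanoid metabolism (-0.36) did not pass. Without RL4452 replicate 1, BMY1 had -0.11 and XTH -0.30, and without RL4452 replicate 2 both LTP3 probe sets were higher in RL4452.

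Probe sets of the same gene or the same transcript cluster were compared because a difference of sequence under 1 probe set can change its signal without a change of transcript level. Several named genes had probe sets that differed in the size or the direction of the difference. For LOC780602, Ta.28514.1.A1_at gave -3.19, while the 4 other probe sets of the gene, from 2 clusters, gave between -0.29 and 0.25. For LOC543448, TaAffx.6140.1.S1_s_at gave -1.77 and the far brighter Ta.27793.2.S1_x_at, of another cluster, gave -0.14. For LOC778392, Ta.351.2.S1_x_at gave -3.13 and Ta.351.1.S1_at -1.48, both past the threshold, and the dim Ta.351.3.S1_at gave 0.23. For LOC542847, both probe sets were lower, Ta.2882.1.S1_at with -1.68 and Ta.2882.1.S1_s_at with -1.02. For LOC100049055, Ta.4725.1.S1_at gave -2.99 and TaAffx.128663.2.S1_at, of another cluster and below the negative control level in both genotypes, gave 0.41. The other named genes, among them GBSS-I and all those higher in RL4452, had 1 named probe set each. For these no such comparison within the gene could be made.

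Over 12737 pairs of probe sets from 4070 clusters, the genotype differences correlated at r = 0.514, and 74.1% had the same sign; probe sets are not independent replicates. The correlation was 0.865 for 2935 pairs of the same sub-cluster, which can share probes, and 0.392 for 9802 pairs of different sub-clusters. Where a probe set passed the threshold, a partner of the same sub-cluster had the same sign in 98.3% of comparisons (95% interval 95.7% to 100%) and a median difference 0.952 times as large. A partner of another sub-cluster had the same sign in 56.8% (44.1% to 80.0%), and the median was 0.0432 times as large. The cluster Ta.10329 alone made 36.5% of these comparisons, and without it the values were 71.3% and 0.211.

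**Figure D3:**
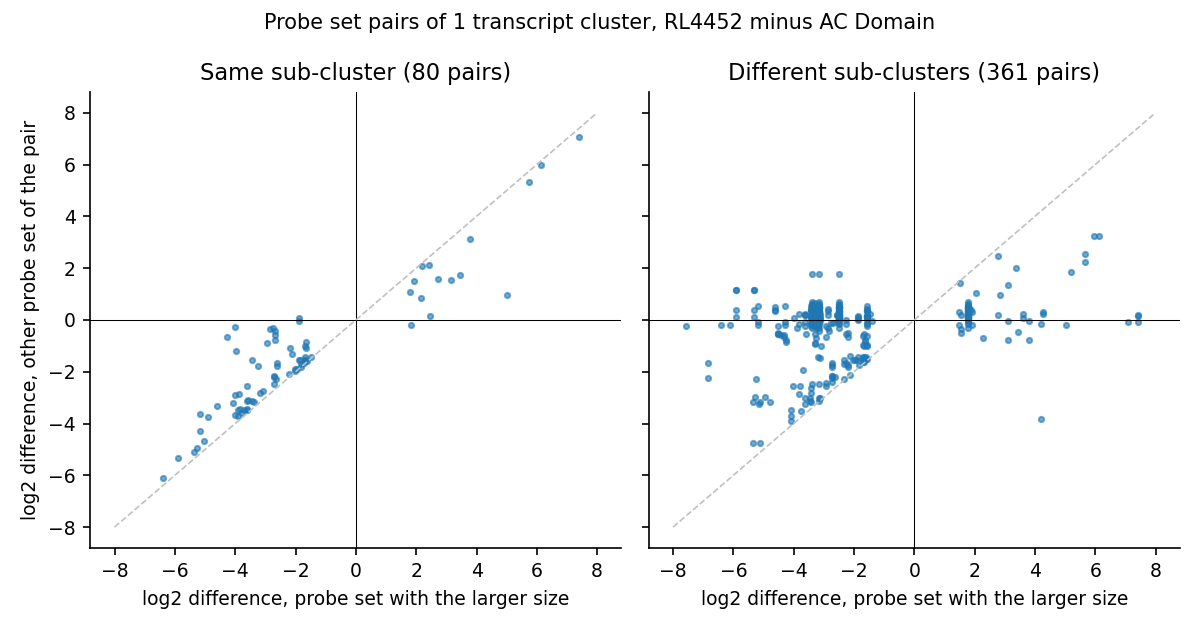
Log2 difference between RL4452 and AC Domain of the probe set with the larger size (x axis) and of its partner (y axis), for 80 pairs of the same sub-cluster (left) and 361 pairs of different sub-clusters (right) with at least 1 probe set past the threshold. Most points of the same sub-cluster lie near the dashed diagonal, while many of different sub-clusters lie along the line at 0.

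Of 25 control probe sets for wheat RNA, 0 passed the threshold with limma and 2 had an unadjusted p under 0.05. The 18S rRNA control had intensities of 2586 and 1914 on the AC Domain arrays and 191 and 432 on the RL4452 arrays, a difference of -2.95 on the log2 scale (standard error 0.43; limma with the controls kept, adjusted p = 0.0859). The 3' probe set of sucrose synthase, an enzyme that splits sucrose for starch synthesis, had -0.92 (adjusted p = 0.161). In 6 of 7 control genes with 3' and 5' probe sets, the 3' minus 5' difference was lowest on the RL4452 replicate 1 array and highest on the RL4452 replicate 2 array. In the other, EF1A, both RL4452 arrays (0.89 and 0.95) lay above both AC Domain arrays (0.69 and 0.62), with a mean 5' signal of 4.07, below the negative control level. The mean 3' signal of GAPDH (3.86) was also below it. For sucrose synthase the 3' minus 5' differences were 4.69 and 6.66 on the RL4452 arrays, against 6.11 and 6.53 on the AC Domain arrays.

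**Figure D4:**
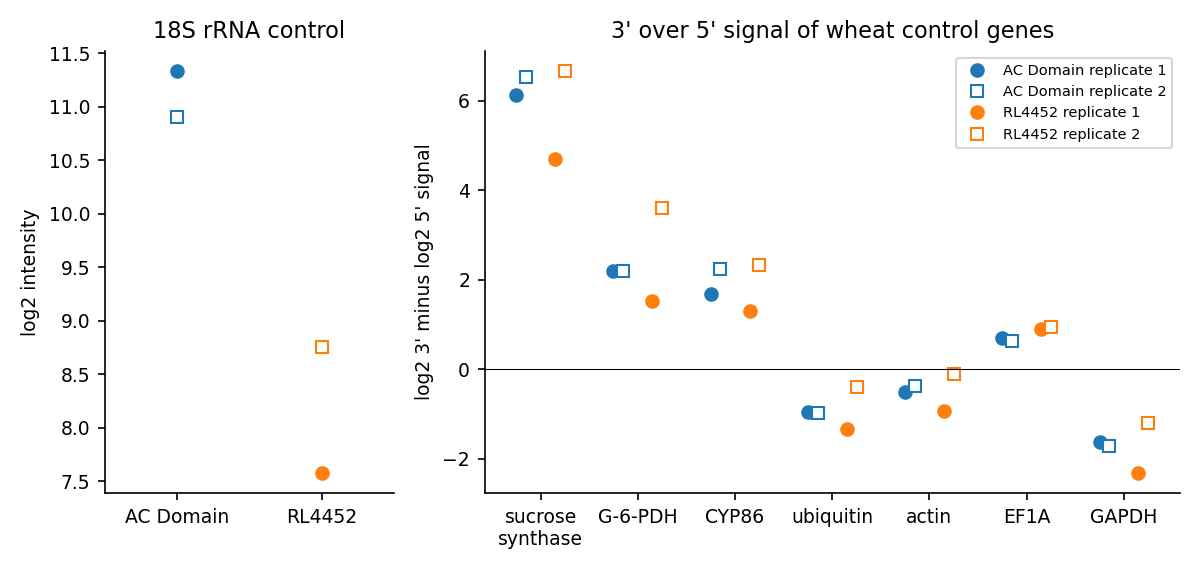
Left, log2 intensity of the 18S rRNA control on each array; right, the difference between log2 3' and log2 5' signal of 7 wheat control genes, with 1 symbol per array. The 18S rRNA signal is lower on both RL4452 arrays, and in 6 of the 7 genes, all but EF1A, the RL4452 arrays lie on opposite sides of the AC Domain arrays.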

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

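The test of the 18S rRNA control, a control probe set left out of the genotype comparison, was chosen after its values had been seen. The 18S rRNA control gave a signal far above the negative controls (22.3) on each of the 4 arrays, and was 7.74-fold brighter in AC Domain (-2.95 on the log2 scale), which missed the threshold (limma, adjusted p = 0.0859). The 2 RL4452 arrays differed from each other as well, at 191 and 432. The 12 control probe sets for poly(A) spikes also varied between arrays. Their mean log2 intensity was 8.28 and 7.74 on the AC Domain arrays and 6.95 and 7.89 on the RL4452 arrays, replicate 1 first. It was thus lowest on RL4452 replicate 1, but did not separate the genotypes. Whether the 18S rRNA control follows the genotype or the poly(A) enrichment of each sample was not tested.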

How the results depend on the processing

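Tests with extended lists, with sub-clusters taken apart and with calls limited to those above the highest negative control were chosen after the data had been seen. The lists themselves were extended after the annotation table and the control probe values had been seen, and before any difference between genotypes was computed. Against 489 calls, the count was 667 with the replicate block, 283 with treat against a 1.5-fold difference, 82 at an adjusted p under 0.01, 2 with the ordinary equal-variance statistic, and between 0 and 1031 without 1 array. It was 0 where an AC Domain array was left out and the lone sample was assumed to vary like the RL4452 pair. The other settings gave 444 to 630 calls. Wherever over 2 were called, 65.9% to 74.6% were lower in RL4452. Of the 489 calls, 486 had a brighter genotype above the highest negative control. Of the 18 named probe sets, 16 passed with the block and 17 with the trend, with no change of sign there or without 1 array. The block did not change the call of the 1 fixed list tested or of the histones, and was not reported for the other lists. Fixed patterns put 0 lists past the threshold; extended lists put 1 there (histones), and also 1 against named probe sets only. The histones missed the threshold with an estimated correlation (camera, adjusted p = 0.710), with fry (0.345), with 1 probe set per gene (0.226, 5 members) and without RL4452 replicate 2 (0.166); the other settings gave 7.79e-05 to 0.0226. For the fixed patterns, a dim-probe filter and 1 probe set per gene left under 5 members. Pairs of 1 cluster had the same sign in 74.1%, in 67.7% with no brightness filter, 61.2% with at least 1 call, 82.8% within and 71.5% between sub-clusters; the cause was not tested. The SD of the genotype difference was 0.499, and 0.638 above the median. Signal limits the rest: 40.6% of probe sets had a mean at or below the 95th percentile of the negative controls.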

Other observations

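The tests of an aborted wash, of degraded RNA and of every explanation for the cluster pattern were chosen only after the result was seen; of the tests of an offset between arrays, that by centring was written before and those by the medians and by quantile normalisation after.

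In the cluster Ta.14571, Ta.14571.1.S1_at was higher in RL4452 by 4.21 on the log2 scale and Ta.14571.2.A1_at differed by -3.81 (limma, adjusted p = 0.0352 and 0.00830). In Ta.10329, with 39 probe sets, Ta.10329.23.S1_at had 1.78, while Ta.10329.16.S1_at had -3.38 and Ta.10329.34.S1_x_at -2.49. These were the 2 clusters of 17 with calls in several sub-clusters in which the calls went both ways, and they were named after their values were seen.

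Calls were more often lower than higher in RL4452, at 72.0%. An offset that lowers every probe set alike on the RL4452 arrays is argued against, since both RL4452 arrays had a higher median than both AC Domain arrays, by a mean of 0.0595 on the log2 scale. After each array was centred on its median 74.6% of the calls were lower, but this moved RL4452 further down, by 0.0595 against calls of at least 1.41, and so decides nothing on its own. An offset that differs with intensity is left open. The upper quartile was lower on the RL4452 arrays (143 and 140) than on the AC Domain arrays (147 and 152). Quantile normalisation, which makes the arrays alike there, left 70.1% of the calls lower (95% binomial interval 65.9% to 74.1%, if probe sets are independent). It changed the differences by -0.10 to 0.14, which is small against calls of at least 1.41, so that it too decides nothing on its own. The array with the aborted wash record is argued against as the whole cause, since 70.2% were lower without it. More degraded RNA in both RL4452 samples alike is argued against by the 3' minus 5' signal. In it the 2 RL4452 arrays lay on opposite sides of the AC Domain arrays in 6 of 7 control genes. Of these 6, GAPDH had a mean 3' signal (3.86) below the negative control level, so that it carries little weight. In the other gene, EF1A, both were higher in RL4452, with a 5' signal also below that level. The 3' minus 5' signal does not argue against more degraded RNA in RL4452 replicate 2 alone, which was the highest array in those 6 genes. A difference between the parents in transcript level or in sequence relative to the array also stays open and was not tested.

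Of 130 called probe sets with a partner in another sub-cluster, 52 had only partners that differed by under 2-fold. Sub-clusters that each match the sequence of 1 genotype would move apart. Of the partners in other sub-clusters of these 130, 3.00% differed at least 2-fold the opposite way (95% interval 0% to 5.71%). The share counts every such partner, and which of them match the other genotype is not known. A low share therefore decides nothing on its own. This cause stays open, and the clusters named above had calls that went both ways. For 34 of these 52 there was a partner in the same sub-cluster, and 94.4% of the 36 pairings had the same sign, but in each of them an ID marks shared sequence, so that this decides nothing. Random error of all 52 is not settled. About 24.5 false calls are expected among the 489 at the threshold (upper limit of the 95% Poisson interval 35, if errors are independent between probe sets). That number takes the error rate of the same fit as exact, although arrays of 1 project deviated together (r = 0.398), so that it decides nothing on its own. Random error of single probe sets among them and a sequence difference under a single probe set may each account for some of these calls and cannot be told apart from a change of 1 transcript of the cluster. Both tests needed a same-sub-cluster partner where neither ID marks shared sequence, and there were 0.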
